A study of Homo sapiens with 12 samples.

How the data were processed

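RNA from MOLM-13 cells was measured in 12 libraries. MOLM-13 is an established acute myeloid leukaemia line that carries an MLL-AF9 fusion and an internal tandem duplication of FLT3. Per the labels' protocols, cells were seeded in triplicate and treated with DMSO, MI-3454, gilteritinib or both agents, and per the series' design text the treatment lasted 8 days. MI-3454 inhibits the binding of menin to MLL1, and gilteritinib is a FLT3 kinase inhibitor. The labels describe ribosomal RNA depletion followed by TruSeq libraries of total RNA. Groups and replicate numbers were taken from the sample titles, which give 4 groups of 3 libraries. A treatment label that should repeat the compound's name carries a different trailing number in 2 of the 3 libraries of each group with MI-3454, whereas the titles name a single compound throughout, so the titles were followed.

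The deposited files hold whole-number counts of reads per gene with no normalization, 1 file per library, with 60668 genes and 5 summary counts in HTSeq's format. The submitters' processing notes name cutadapt 2.1, STAR 2.7.1a, HTSeq 0.11.2, DESeq2 and the genome build GRCh38, without saying which step each served. The annotation release and the strand setting of the counting are not given in the sources used here. Reads that fall in a gene and in its antisense partner may therefore not be told apart, and the counts of antisense or overlapping genes are uncertain. HTSeq's default leaves out reads placed at several positions, so genes with near-identical copies can lose reads. The HLA genes, TPSAB1 and TPSB2, CCL4, HSPA1B, the ribosomal protein genes and the histone genes are uncertain in this respect. Gene symbols came from a table of gene names joined on the Ensembl identifier without its version, which matched 60295 of the 60668 genes. Biotypes and coordinates came from GENCODE release 29 on GRCh38, which matched 58561. Of the 1377 entries that shared a symbol with another entry, the entry with the most counts kept the symbol.

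Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. A gene was tested if it passed edgeR's filterByExpr with the 4 groups over all 12 libraries, which kept 13972 of the 30849 genes with at least 1 count. Each pair of groups was compared in its own quasi-likelihood fit with TMM scaling among its 6 libraries, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The interaction term was fitted to all 12 libraries and measures how far the combination's log2 change departs from the sum of the log2 changes under each single agent. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Expression levels are counts per 1e6 counts (CPM) with TMM scaling over the 12 libraries, given as mean ± SD with n = 3 per group. Where a group had no counts for a gene in any of its 3 libraries, the fold was computed against a floor of 3 counts over the group and is given as a lower bound. Where a group had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only. The p-values measure the spread between separately seeded cultures of a single cell line, and nothing in the labels says that the cultures were grown on separate days.

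Most named genes followed a rule fixed in advance. For each comparison against DMSO, it names 10 anchor genes (MEIS1, HOXA9, MEF2C, FLT3, PIM1, DUSP6, MYC, BCL2, ITGAM and MEN1). It adds the 6 protein-coding genes with the largest called rise and the 6 with the largest called fall, given at least 5 CPM in the higher group and no overlap of CPM between the groups. From each gene list described it takes up to 4 called members with the largest log2 change. For the combination against each single agent and for the interaction, the rule names the 4 largest changes in each direction, with no condition on overlap for the interaction. For genes beyond both single agents, it names the 5 in each direction with the largest smaller change of both comparisons. List members that were not called may be named with their values. Other genes named for the interaction, and the genes whose levels with DMSO close the text, lie outside this rule.

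The 39 gene lists, with 699 entries that all matched, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with limma's camera on voom-weighted log2 CPM with a preset correlation of 0.01 between genes, and p was adjusted over the 35 lists with at least 3 tested members. Camera was also run with a correlation estimated for each list, and fry tested whether a list's genes moved together. The lists with fewer than 3 tested members have counts only. A count "adjusted over the list alone" uses Benjamini-Hochberg adjustment within that list.

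On simulated counts with the libraries' own means and sizes, 200 of the 13972 genes were changed by known folds. Of 50 genes changed 2-fold, the test recovered 78% for MI-3454 against DMSO, 72% for gilteritinib, 76% for the combination and 56% for the interaction, and called 3, 10, 13 and 6 unchanged genes. For 4-fold changes it recovered 94%, 92%, 92% and 82%. Each gene was drawn independently and the directions were random, so these figures leave out deviations that libraries share. Nor do they cover scaling where most genes change, as with the 8037 genes called under the combination against DMSO. Alternatives covered DESeq2 1.42.0 (its size factors and its Wald test), scaling by total counts, no filter, a stricter filter of 1 CPM in 3 libraries, protein-coding genes only, all 12 libraries in a single fit, a replicate block, a 2-fold minimum and leaving out each library. Leaving out 4 libraries together, subtracting a genomic background, and leaving out each library from the overlaps were chosen after seeing the data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.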

Results

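RNA was measured in MOLM-13 cells after 8 days with DMSO, the menin-MLL1 inhibitor MI-3454, the FLT3 inhibitor gilteritinib or both agents, with 3 libraries per group. MOLM-13 is an acute myeloid leukaemia line in which an MLL fusion protein and a constitutively active FLT3 receptor are both present. The design asks what each treatment changes relative to DMSO and how far the lists of changed genes overlap. Gene counts per library were 11.1, 11.1 and 9.02 M with DMSO, 12.1, 9.03 and 9.14 M with gilteritinib, 8.98, 9.41 and 9.93 M with MI-3454, and 11.3, 8.84 and 6.47 M with the combination.

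The groups separated on the first principal component of log2 CPM, which held 62.3% of the variance and ordered them as DMSO, gilteritinib, MI-3454 and combination. A second component held 12.5%. Within every group, 1 library had the highest share of counts in RN7SL1, the RNA of the signal recognition particle: DMSO 2, gilteritinib 2, MI-3454 3 and combination 1. Their shares were 4.27%, 2.88%, 4.56% and 1.66%. Below, "the 4 libraries highest in RN7SL1" means these libraries, each the highest within its own group only. The share in combination 1 lay below that of every library of the other groups. The deviations of these 4 libraries from their group means correlated with each other across genes, with r from 0.21 to 0.51 (genes are not independent replicates). Mitochondrially encoded genes took 2.84% of counts in gilteritinib 2 and 1.37% in DMSO 2, against a mean of 0.877% ± 0.0869 (SD, n = 3) with the combination. Reads placed uniquely but outside annotated exons, introns included, made up 18.1% ± 2.03 (SD, n = 3) of uniquely placed reads with DMSO, 21.0% ± 4.13 with MI-3454 and 32.6% ± 4.02 with the combination. With gilteritinib they lay between 15.6% and 17.8%. The combination libraries all lay above the DMSO libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give), whereas the exact permutation p was 0.3 for MI-3454 and 0.6 for gilteritinib.

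**Figure D1:**
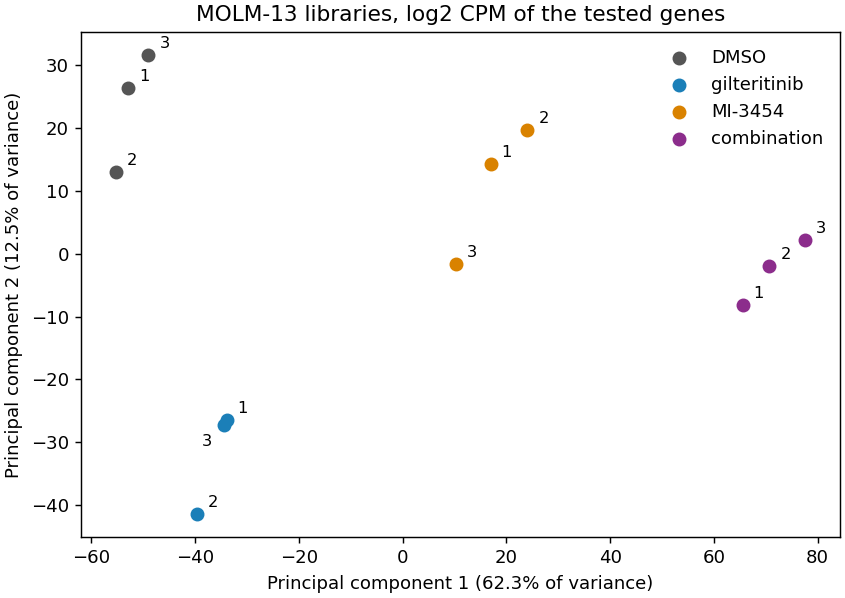
Principal components 1 and 2 (arbitrary units) of log2 CPM over the 13972 tested genes, 1 point per library, numbered by replicate and coloured by group. The groups lie apart along component 1, which holds 62.3% of the variance, with DMSO and the combination at its ends.

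**Figure D2:**
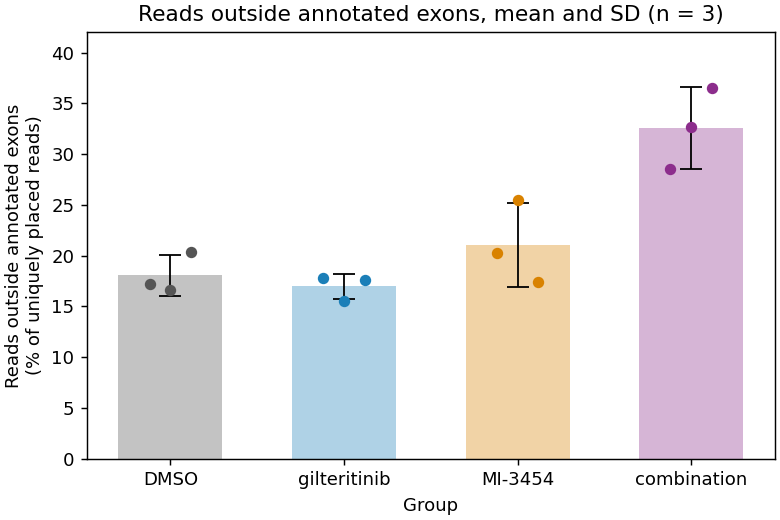
Percent of uniquely placed reads that fell outside annotated exons, with points for libraries, bars for group means and error bars for SD (n = 3). The combination libraries lie between 28.5% and 36.5%, above all libraries of the other groups.

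MI-3454 lowered genes that MLL fusion proteins are known to drive and raised genes of myeloid maturation. MEIS1 (ENSG00000143995.20, chromosome 2, 66433452 to 66573869), a HOX cofactor of leukaemic self-renewal, fell 6.16-fold from 67.7 ± 5.58 CPM (SD, n = 3), a log2 change of -2.62 ± 0.14 (SE). MEF2C, another transcription factor gene of this program, fell by 2.35 ± 0.13, FLT3 itself by 1.61 ± 0.14 and the survival gene BCL2 by 1.30 ± 0.12 on the log2 scale. HOXA9 (ENSG00000078399.18, chromosome 7, 27162435 to 27175180) fell by 0.70 ± 0.11, from 62.4 ± 2.53 to 38.3 ± 1.42 CPM. In the HOXA cluster, 8 of 10 tested genes fell and none rose (8 adjusted over the list alone; limma camera adjusted p = 2.45e-06, and adjusted p = 0.122 with an estimated correlation), with log2 changes of -2.38 for HOXA6, -2.24 for HOXA3 and -2.11 for HOXA5. Of 21 other MLL-fusion target genes tested, 14 fell and 3 rose (14 and 3 adjusted over the list alone; adjusted p = 2.94e-09, 0.106 with an estimated correlation), with ZNF521 at -1.63, and without DMSO 1 the number that rose was 1. MEN1, which encodes menin, had a log2 change of -0.08 ± 0.17 that did not pass the test (edgeR adjusted p = 0.8). Across all genes, 2658 of 13972 changed (edgeR quasi-likelihood), 1407 higher and 1251 lower, of which 652 and 520 changed at least 2-fold. With the replicate number as a block, 1678 genes changed. Deviations of same-numbered DMSO and MI-3454 libraries from their group means correlated at 0.20, -0.31 and -0.39 across genes. The replicate number thus did not mark pairs in this comparison.

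Granule, monocyte and neutrophil genes were among those that rose under MI-3454. Of 12 primary granule genes, 10 rose and none fell (12 adjusted over the list alone; limma camera adjusted p = 2.49e-13, and adjusted p = 0.106 with an estimated correlation). MPO (ENSG00000005381.8, chromosome 17, 58269856 to 58280935), the peroxidase of azurophil granules, rose 4.19 ± 0.15 on the log2 scale to 609 CPM, MS4A3 rose 2.63 and RNASE2 rose 2.18. Of 20 tested monocyte and macrophage genes, 15 rose and none fell (15 adjusted over the list alone; adjusted p = 1.39e-13, 0.037 with an estimated correlation). The lipopolysaccharide co-receptor gene CD14 rose 5.39 ± 0.35, MNDA rose 4.88 ± 0.18 and CYBB, a subunit of the phagocyte oxidase, rose to 247 CPM, whereas ITGAM (CD11b) had a log2 change of 0.04 ± 0.13 (adjusted p = 0.89). FCN1 had no counts with DMSO and was at least 11-fold higher with MI-3454. Among 14 neutrophil maturation genes 11 rose and none fell (11 adjusted over the list alone; adjusted p = 2.51e-11, 0.106 with an estimated correlation), with FCAR at 4.84 ± 0.23 and S100A9 at 4.20 ± 0.31. The list's median log2 change of 2.99 was the same to 2 decimals with FPR2, which had no counts with DMSO, at its bound of at least 12.5-fold. The largest rises of all protein-coding genes within the naming rule were in NAV3 (7.25 ± 0.19), SERPINB10 (6.91 ± 0.24), CR1 (6.72 ± 0.40), CYP4F3 (6.17 ± 0.33), HP (5.89 ± 0.26) and SERPINA1 (5.79 ± 0.39).

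Antigen presentation of class II, interferon response and amino acid synthesis genes fell under MI-3454. HLA-DRA fell by 4.56 ± 0.22 on the log2 scale and its regulator CIITA by 1.57 ± 0.21, and 5 of 6 tested MHC class II genes fell with none higher (5 adjusted over the list alone; limma camera adjusted p = 5.01e-05, and adjusted p = 0.122 with an estimated correlation). All 3 tested dendritic cell genes fell (3 adjusted over the list alone; adjusted p = 0.00162, 0.122 with an estimated correlation), BATF3 by 4.82 ± 0.42. Of 22 interferon-stimulated genes, 8 fell and 2 rose (12 and 3 adjusted over the list alone; adjusted p = 0.002, 0.106 with an estimated correlation), with IFIT1 at -4.36 ± 0.33 and IFIT2 at -2.92 ± 0.16. The number that rose was 1 without DMSO 1, DMSO 3 or MI-3454 1. ATF4 and amino acid synthesis genes, induced in the response to amino acid shortage, fell in 17 of 21 cases and rose in none (18 adjusted over the list alone; adjusted p = 1.39e-13, 0.091 with an estimated correlation), DDIT4 by 2.36 ± 0.16 and CHAC1 by 1.72 ± 0.17. FOXO target genes went the other way, 11 of 16 higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 2.29e-06, 0.106 with an estimated correlation), with SESN3 at 2.97 ± 0.21 and IRS2 at 2.43 ± 0.14. Receptor tyrosine kinase genes were lower in 4 and higher in 2 of 9 cases (5 and 2 adjusted over the list alone; adjusted p = 0.0542), AXL among the lower at -2.27 ± 0.25. MYC, at -0.55 ± 0.13, was called (adjusted p = 0.01) but not without MI-3454 1 (adjusted p = 0.057) or MI-3454 2 (0.052). Its call also ended with the replicate number as a block (edgeR adjusted p = 0.063). The largest falls within the naming rule were in CD80, which had no counts with MI-3454 and was at least 54.6-fold lower, ALDH1A3 (-7.16 ± 0.36), RHBDL3 (119-fold lower, exact 95% interval 32.6 to 988 from 2 counts), IL2RA (-5.66 ± 0.18), JCAD (-4.95 ± 0.27) and SPIB (-4.94 ± 0.36).

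Gilteritinib lowered known targets of the kinase signal and the amino acid response while genes of mitosis rose. PIM1 (ENSG00000137193.14, chromosome 6, 37170203 to 37175426), a kinase gene induced by STAT5, fell from 930 to 50.4 CPM, a log2 change of -4.20 ± 0.13 (SE, n = 3 per group). CISH, a STAT5-induced feedback inhibitor, fell by 2.20 ± 0.13 and OSM by 1.81 ± 0.14. PIM1 was also called lower with MI-3454 alone, at 274, 253 and 299 CPM in its libraries. IL2RA kept 1 count with gilteritinib against 1706 with DMSO, a ratio of 1620 (exact 95% interval 291 to 64100). Of 16 STAT5 target genes, 7 fell and 3 rose (8 and 3 adjusted over the list alone; limma camera adjusted p = 0.00178, and adjusted p = 0.272 with an estimated correlation). MAPK feedback and output genes fell in 5 and rose in 2 of 18 cases (6 and 2 adjusted over the list alone; adjusted p = 0.488), EGR3 at -0.99 ± 0.13, and DUSP6 and FOS higher at 0.78 ± 0.14 and 0.83 ± 0.12. ATF4 and amino acid synthesis genes fell in 19 of 21 cases and rose in none (19 adjusted over the list alone; adjusted p = 3.47e-26, 0.0336 with an estimated correlation), with CHAC1 at -3.46 ± 0.17, the asparagine synthetase gene ASNS at -3.13 ± 0.26 and ALDH1L2 at -2.14 ± 0.14.

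Among fusion targets under gilteritinib, MEIS1 was higher by 0.46 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0091) and HOXA9 was at -0.13 ± 0.10 (adjusted p = 0.41). The HOXA list had a median of 0.07 (camera adjusted p = 0.488). HOXA7 was called higher, a call that ended without DMSO 1 (0.61, edgeR adjusted p = 0.055) or gilteritinib 3 (0.61, 0.059). MEF2C, at -0.32 ± 0.11, lay near the threshold (adjusted p = 0.067). It passed with DESeq2's Wald test (adjusted p = 0.041), with all 12 libraries fitted together (0.03), with the replicate number as a block (0.0005), without DMSO 2 (0.0079) and without the 4 libraries highest in RN7SL1 (0.00095). FLT3 and BCL2, at -0.42 ± 0.12 and -0.44 ± 0.11, passed the test with all libraries (adjusted p = 0.033 and 0.018). Both calls ended without DMSO 1 (0.15 and 0.06), DMSO 3 (0.089 and 0.069), gilteritinib 1 (0.075 and 0.063), gilteritinib 2 (0.096 and 0.054) or gilteritinib 3 (0.1 and 0.08). MYC fell by 0.60 ± 0.12, ITGAM had a log2 change of -0.01 ± 0.10 (adjusted p = 0.95) and MEN1 of 0.14 ± 0.13 (adjusted p = 0.51).

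Genes of the cell cycle were higher with gilteritinib. G2 and M phase genes rose in 17 of 23 cases and fell in none (20 adjusted over the list alone; limma camera adjusted p = 4.71e-13, and adjusted p = 0.148 with an estimated correlation), with CDC20 at 1.01 ± 0.11 and MKI67 at 0.98 ± 0.11 on the log2 scale. The number was 11 without gilteritinib 3. CDC20, KIF20A and CENPF were also called higher with MI-3454 alone. Those calls ended with the replicate number as a block (edgeR adjusted p = 0.11, 0.08 and 0.082). MKI67 was also called with MI-3454 alone, with no overlap of CPM with the DMSO libraries, and its call did not end with the block. S phase genes rose in 12 of 25 cases (16 adjusted over the list alone; adjusted p = 3.27e-08, 0.269 with an estimated correlation), with 7 without DMSO 1 and 6 without gilteritinib 1, and 1 fell without DMSO 2 or without the 4 libraries highest in RN7SL1. Of 29 replication-dependent histone genes 2 rose (2 adjusted over the list alone; adjusted p = 2.54e-07, 0.499 with an estimated correlation), and 25 rose without DMSO 2 or without those 4 libraries, 4 with total counts, while 1 rose without DMSO 1, DMSO 3 or gilteritinib 2. Of the 13 mitochondrially encoded genes none passed with edgeR (10 higher adjusted over the list alone; median log2 change 1.87, adjusted p = 0.00178, 0.589 with an estimated correlation), whereas 12 passed without DMSO 2, 8 without gilteritinib 1, 3 without gilteritinib 3, and 13 without the 4 libraries that were highest in RN7SL1. Gilteritinib 2, the highest of its group in RN7SL1, held the largest mitochondrial share of all 12 libraries, 2.84%.

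Granule and mast cell genes rose with gilteritinib, and MHC class II and interferon genes fell. All 4 tested markers of mast cells, basophils and eosinophils rose (4 adjusted over the list alone; limma camera adjusted p = 4.06e-07, and adjusted p = 0.0937 with an estimated correlation). PRG2, the eosinophil major basic protein gene, rose 3.08 ± 0.29 on the log2 scale, EPX rose 1.94 ± 0.11 to 145 CPM and TPSB2, a mast cell tryptase with a near-identical copy in TPSAB1, rose 2.20 ± 0.20. Primary granule genes rose in 7 of 12 cases and fell in none (9 adjusted over the list alone; adjusted p = 4.06e-07, 0.201 with an estimated correlation), with AZU1 at 1.02 ± 0.15 and ELANE at 0.96 ± 0.13. In this list 1 fell without the 4 libraries highest in RN7SL1. Of 8 stem and progenitor genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0661, 0.349 with an estimated correlation and 0.0362 with the replicate number as a block), among them ANGPT1 at 1.02 ± 0.15 and GATA2 at 0.83 ± 0.12. MHC class II genes fell in 5 of 6 cases (6 adjusted over the list alone; adjusted p = 4.06e-07, 0.0937 with an estimated correlation), with HLA-DRA at -6.81 ± 0.33 and HLA-DRB1 189-fold lower (exact 95% interval 33.6 to 7510). Interferon-stimulated genes fell in 10 of 22 cases and rose in none (12 adjusted over the list alone; adjusted p = 4.06e-07, 0.0937 with an estimated correlation), IFIT2 by 1.87 ± 0.14.

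In all, 2110 genes changed with gilteritinib (edgeR quasi-likelihood), 967 higher and 1143 lower, of which 219 and 379 changed at least 2-fold. The largest rises within the naming rule were in SLC6A13 (3.43 ± 0.17), IRX3 (3.27 ± 0.15), ADAMTS7 (3.16 ± 0.37), PRG2, CSRP3 (2.56 ± 0.34) and IQSEC3 (2.36 ± 0.29). Beside IL2RA, HLA-DRB1 and HLA-DRA, the largest falls were in RHBDL3 (83.3-fold, exact 95% interval 28.2 to 407), CD80 (86-fold, 23.5 to 716) and SLC6A9 (-5.69 ± 0.50). This count depended on single libraries: it was 1271 without DMSO 1, 3985 without DMSO 2, 1307 without DMSO 3, 1267 without gilteritinib 1, 1401 without gilteritinib 2 and 1243 without gilteritinib 3. It was 4250 without the 4 libraries that were each highest in RN7SL1 within their group, and 4928 with the replicate number as a block. Deviations of same-numbered DMSO and gilteritinib libraries correlated at 0.14, 0.39 and 0.11 across genes. The 0.39 belongs to DMSO 2 and gilteritinib 2, both among the 4 libraries highest in RN7SL1. Pairs of different number ran from -0.30 (DMSO 2 with gilteritinib 1) to 0.21 (DMSO 3 with gilteritinib 1).

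**Figure D3:**
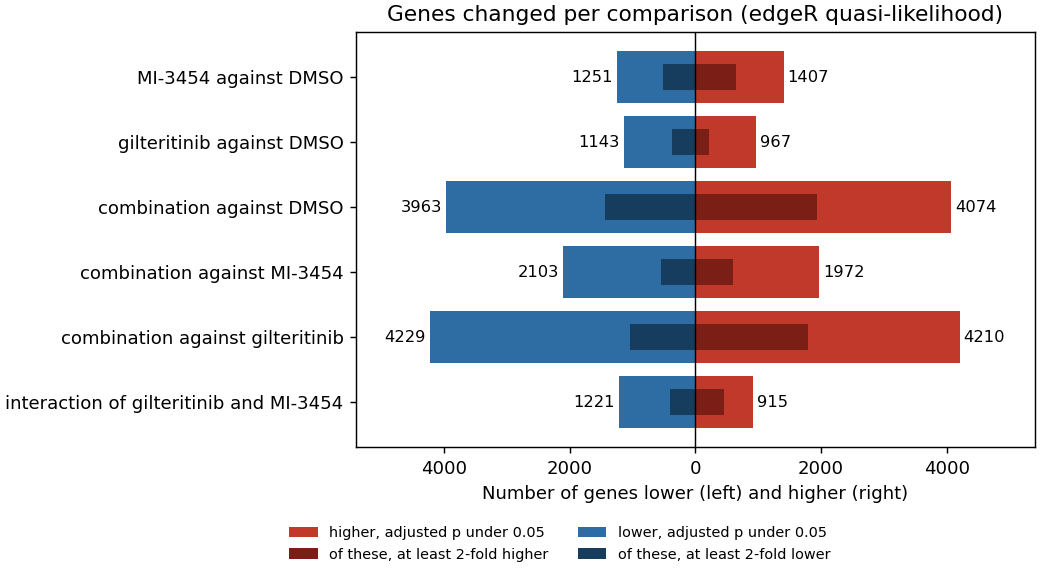
Number of genes called higher (right) and lower (left) in each comparison (edgeR quasi-likelihood, adjusted p under 0.05), with the genes that also changed at least 2-fold in the darker bars. The combination changed 8037 genes against DMSO, MI-3454 2658 and gilteritinib 2110.

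With both agents, MEIS1, MEF2C and most tested HOXA cluster genes fell, as did most sterol, fatty acid and amino acid synthesis genes. Camera called 22 lists with the preset correlation and 0 with an estimated correlation. MEIS1 fell by 3.71 ± 0.17 on the log2 scale to 5.12 CPM (SE, n = 3 per group), MEF2C by 4.18 ± 0.13, BCL2 by 2.23 ± 0.11, FLT3 by 1.87 ± 0.11 and HOXA9 by 1.08 ± 0.11. PIM1 fell by 3.79 ± 0.13 and MYC (ENSG00000136997.19, chromosome 8, 127735434 to 127741434) by 1.95 ± 0.13, from 702 to 182 CPM. HOXA cluster genes fell in 8 of 10 cases (8 adjusted over the list alone; limma camera adjusted p = 0.000891, and adjusted p = 0.182 with an estimated correlation), and 1 rose without the 4 libraries highest in RN7SL1. STAT5 target genes fell in 11 and rose in 3 of 16 cases (11 and 3 adjusted over the list alone; adjusted p = 0.000891, 0.164 with an estimated correlation), with SOCS2 at -6.04 ± 0.15. MAPK feedback and output genes fell in 14 and rose in 2 of 18 cases (15 and 2 adjusted over the list alone; adjusted p = 0.000143, 0.178 with an estimated correlation), EGR3 by 6.24 ± 0.28 and EGR1 by 2.17 ± 0.18, while DUSP6 rose 0.99 ± 0.13. MEN1 was called lower (-0.36 ± 0.13, edgeR adjusted p = 0.026), a call that ended without combination 2 (0.077), combination 3 (0.099) or DMSO 2 (0.079), with total-count scaling (0.1) and with protein-coding genes only (0.071).

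Genes of amino acid, sterol and fatty acid synthesis, glycolysis and ribosome biogenesis fell under the combination, as did heat shock genes. ATF4 and amino acid synthesis genes fell in 19 and rose in 1 of 21 cases (19 and 1 adjusted over the list alone; limma camera adjusted p = 3.76e-14, and adjusted p = 0.108 with an estimated correlation), with none higher without DMSO 1, combination 2 or combination 3 and 2 higher with total counts. Among those that fell were PHGDH, the first enzyme of serine synthesis, at -4.25 ± 0.14 (347 to 18.1 CPM) and CHAC1 at -7.09 ± 0.25. Of 20 cholesterol synthesis genes all fell (20 adjusted over the list alone; adjusted p = 3.05e-10, 0.164 with an estimated correlation), HMGCS1 by 2.85 ± 0.14 and DHCR7 by 2.08 ± 0.13. Fatty acid synthesis genes fell in 10 of 11 cases (11 adjusted over the list alone; adjusted p = 1.76e-07, 0.164 with an estimated correlation), the desaturase gene SCD by 3.16 ± 0.14, and FASN had a log2 change of -2.09 ± 0.13. MYC and ribosome biogenesis genes fell in 22 of 23 cases (22 adjusted over the list alone; adjusted p = 1.3e-11, 0.164 with an estimated correlation), with NOLC1 at -1.60 ± 0.11. Glycolysis genes fell in 17 and rose in 2 of 21 cases (17 and 2 adjusted over the list alone; adjusted p = 1.74e-06, 0.2 with an estimated correlation), the aldolase gene ALDOC by 4.70 ± 0.20 and the lactate transporter gene SLC16A1 by 2.58 ± 0.13. Heat shock genes fell in 9 and rose in 1 of 12 cases (9 and 1 adjusted over the list alone; adjusted p = 0.00108, 0.197 with an estimated correlation), HSPD1 by 1.32 ± 0.11. Heat shock genes rose in 2 cases without DMSO 2 or without the 4 libraries highest in RN7SL1. Nuclear genes of oxidative phosphorylation had a median log2 change of -0.04, with 4 lower and 1 higher of 30 (0 and 1 adjusted over the list alone; adjusted p = 0.621, 0.861 with an estimated correlation). With total counts the median was 0.07, with 1 lower and 4 higher. The lower and higher numbers were 2 and 2 without DMSO 1, 6 and 3 without DMSO 2, 0 and 1 without combination 2 or combination 3, and 8 and 3 without the 4 libraries.

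Genes of maturation, MHC class I and lysosomes rose under the combination, whereas MHC class II genes fell. All 14 tested neutrophil maturation genes rose (14 adjusted over the list alone; limma camera adjusted p = 1.95e-08, and adjusted p = 0.108 with an estimated correlation), FCAR by 5.89 ± 0.20 and S100A9 by 5.59 ± 0.25 on the log2 scale, with a median of 3.28, or 3.17 with FPR2 at its bound. Of 20 monocyte and macrophage genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 7.9e-07, 0.108 with an estimated correlation), with CYBB at 5.11 ± 0.12, and ITGAM rose 0.39 ± 0.10. MHC class I and antigen processing genes rose in 11 of 15 cases and fell in none (11 adjusted over the list alone; adjusted p = 6.4e-05, 0.164 with an estimated correlation), with HLA-F at 3.97 ± 0.25 and their regulator NLRC5 at 2.68 ± 0.12. MHC class I genes were lower in 1 case without DMSO 2 or without the 4 libraries highest in RN7SL1. MHC class II genes fell in 4 of 6 cases and rose in none (6 lower adjusted over the list alone; adjusted p = 0.00302, 0.164 with an estimated correlation), HLA-DRA by 5.89 ± 0.23. Lysosome and autophagy genes rose in 20 of 25 cases and fell in 1 (20 and 1 adjusted over the list alone; adjusted p = 1.61e-06, 0.183 with an estimated correlation), with WIPI1 at 2.14 ± 0.18 and the cathepsin gene CTSD at 1.86 ± 0.14. None fell without DMSO 1, combination 1 or combination 3 or with total counts. FOXO target genes rose in 12 and fell in 1 of 16 cases (12 and 1 adjusted over the list alone; adjusted p = 0.000102, 0.164 with an estimated correlation), with SESN3 at 3.37 ± 0.15. The number that fell was 2 without DMSO 2 or without the 4 libraries.

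Cell cycle genes fell in part under the combination. S phase genes fell in 17 and rose in 1 of 25 cases (17 and 1 adjusted over the list alone; limma camera adjusted p = 0.00129, and adjusted p = 0.248 with an estimated correlation), with the clamp loader gene RFC3 at -0.81 ± 0.13 and the licensing factor gene CDT1 at -0.99 ± 0.14. None rose without combination 1. Replication-dependent histone genes fell in 26 of 29 cases (28 adjusted over the list alone; adjusted p = 7.9e-07, 0.412 with an estimated correlation), H1-3 by 1.58 ± 0.14. The G2 and M phase list had 4 higher and 4 lower of 23 (4 and 4 adjusted over the list alone; adjusted p = 0.675), MKI67 rising 0.80 ± 0.10. Of them 2 were lower without DMSO 1, combination 2 or combination 3. It had 6 higher and 1 lower with total counts, where the median moved from 0.03 to 0.13, and 6 higher and 7 lower without the 4 libraries highest in RN7SL1.

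Of all 13972 genes, 8037 changed, 4074 higher and 3963 lower, and 1929 were at least 2-fold higher against 1432 at least 2-fold lower (edgeR quasi-likelihood). Scaling by total counts shifted the median log2 change by 0.10 and put 59.2% of the called genes on the higher side, against 50.7% with TMM. The largest rises within the naming rule were in SERPINB2, which had no counts with DMSO and was at least 78.8-fold higher, NAV3 (8.19 ± 0.17), SERPINB10 (7.75 ± 0.19), TLR8 (271-fold, exact 95% interval 48.1 to 10700), HP (7.05 ± 0.24) and KCNJ2 (139-fold, 38.1 to 1160). With no counts left in the combination, PKDCC was at least 232-fold lower, XIRP1 at least 208-fold, CD276 at least 135-fold and CAVIN1 at least 105-fold. ADM2 fell 849-fold (235 to 7020) and IL2RA 775-fold (214 to 6410).

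Lists that camera did not call under the combination held single genes that changed. Among 14 genes of menin, MLL1 and partner proteins, 6 fell and 1 rose (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.276, and adjusted p = 0.427 with an estimated correlation). DOT1L, a histone methyltransferase recruited by MLL fusion proteins, fell by 0.82 ± 0.12 on the log2 scale. KMT2A, which encodes MLL1, rose 0.76 ± 0.10, and without DMSO 2 the number that rose was 2. With total counts 3 of the 14 genes were lower and 2 higher, and without the 4 libraries highest in RN7SL1 7 were lower and 2 higher. The BCL2 family had 5 lower and 3 higher of 14 (the same numbers adjusted over the list alone; adjusted p = 0.308, 0.448 with an estimated correlation), with BMF higher at 0.92 ± 0.11. The p53 targets had 7 lower and 3 higher of 17 (8 and 3 adjusted over the list alone; adjusted p = 0.0887, 0.346 with an estimated correlation), with SESN2 at -2.41 ± 0.12. NF-kB and inflammatory cytokine genes had 9 lower and 5 higher of 15 (9 and 5 adjusted over the list alone; adjusted p = 0.0862, 0.218 with an estimated correlation), with CCL3 at -3.54 ± 0.25 and CXCL8 at 2.79 ± 0.23. Cell cycle inhibitors had 5 lower and 3 higher of 12 (5 and 3 adjusted over the list alone; adjusted p = 0.417, 0.476 with an estimated correlation), with CDKN1A at -1.38 ± 0.12 and BTG1 at 1.52 ± 0.11. DNA methyltransferase, TET and polycomb genes had 6 lower and 3 higher of 15 (6 and 3 adjusted over the list alone; adjusted p = 0.435, 0.484 with an estimated correlation), with TET2 at 1.41 ± 0.11.

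Markers of other cell types were mostly untested because they were hardly expressed. Both tested T cell markers fell under the combination (2 adjusted over the list alone), TRAC by 4.23 ± 0.28 on the log2 scale. TRAC also fell with MI-3454 alone, by 1.92 ± 0.23, but rose 1.18 ± 0.14 with gilteritinib alone. The only tested B cell marker, IGKC, fell 154-fold (exact 95% interval 42.2 to 1270; 1 adjusted over the list alone). The only tested megakaryocyte marker, ITGA2B, fell by 1.82 ± 0.43 (1 adjusted over the list alone). The erythroid marker EPOR rose 0.55 ± 0.17 (1 adjusted over the list alone), a call that ended without DMSO 1 (edgeR adjusted p = 0.072). Of 3 fibroblast and epithelial markers 1 fell (1 adjusted over the list alone; limma camera adjusted p = 0.278, and adjusted p = 0.403 with an estimated correlation), KRT18 by 1.22 ± 0.21. With gilteritinib alone COL1A1 rose 1.41 ± 0.33.

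**Figure D4:**
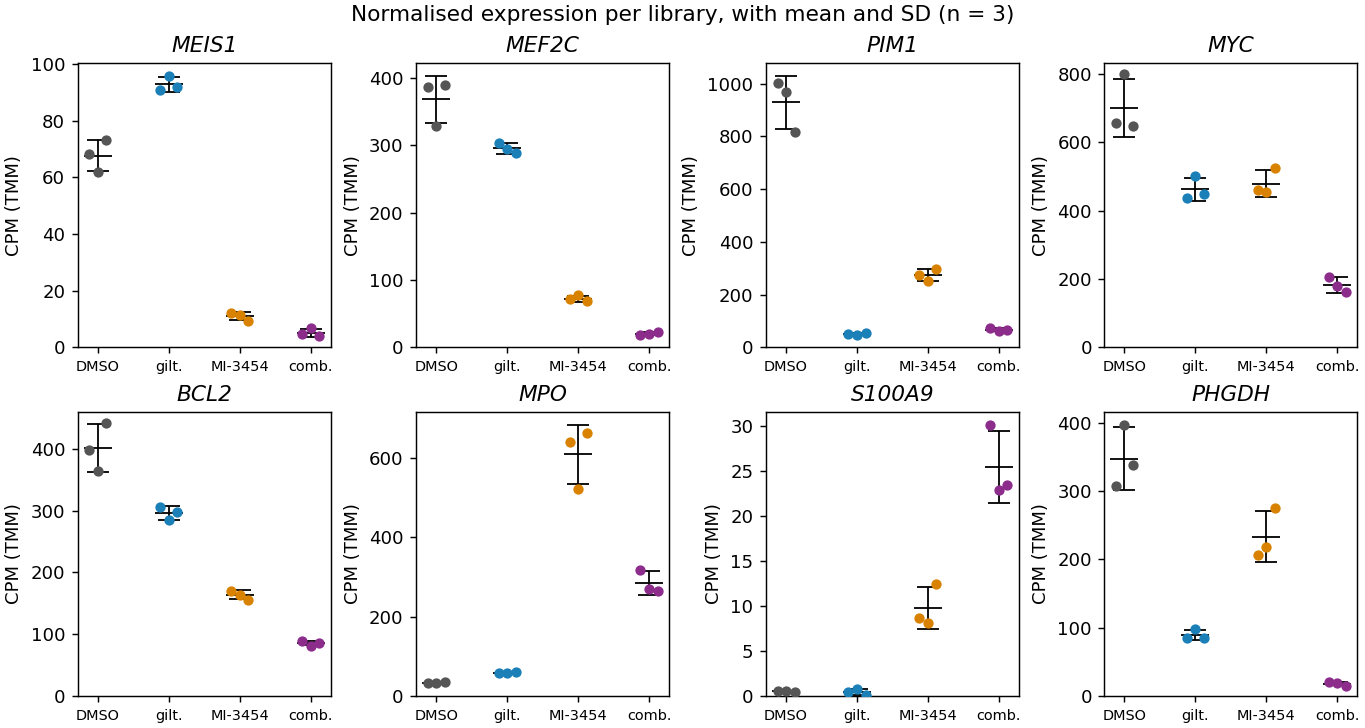
Normalised expression in CPM of 8 genes, with points for libraries, a dash for the group mean and error bars for SD (n = 3), on linear axes that start at 0. MEIS1, MEF2C, BCL2 and MYC are lowest with the combination, PIM1 is lowest with gilteritinib at 50.4 CPM, MPO is highest with MI-3454 at 609 CPM, S100A9 is highest with the combination at 25.5 CPM and PHGDH is lowest there at 18.1 CPM.

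The lists of changed genes overlapped in their directions. In all 3 comparisons with DMSO, 400 genes were higher and 545 lower, 945 in all, and the total was 585 without DMSO 1, 618 without DMSO 3 and 1694 without the 4 libraries highest in RN7SL1. MI-3454 and gilteritinib shared 415 higher and 567 lower genes, where independent lists would share 97.4 and 102, and 82 genes went in opposite directions. MI-3454 and the combination shared 1300 higher and 1183 lower genes (410 and 355 for independent lists), with 14 opposite, so that 93.4% of MI-3454's calls were also called under the combination in the same direction. For gilteritinib the shared numbers were 593 and 866 (282 and 324 for independent lists), with 197 opposite, and the share of its calls was 69.2%. In 20 simulations, controls and unchanged groups were all drawn anew from the DMSO means, each gene independently. A mean of 0.05 or fewer genes was shared. Unchanged groups give hardly any calls, and the draw leaves out deviations that libraries share. The number therefore sets no limit on what the shared controls add. The log2 changes across genes correlated at 0.47 between the single agents, 0.86 between MI-3454 and the combination and 0.46 between gilteritinib and the combination. The mean over the simulations was 0.49 for each of these pairs. The covariances exceeded the simulated ones by 0.177, 0.809 and 0.291. No split of 3 DMSO libraries leaves at least 2 on both sides, so comparisons against separate controls were not run, and part of the excess over independent lists may come from the shared controls.

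Direct comparisons with each single agent showed what the combination added. Against MI-3454, 4075 genes changed (edgeR quasi-likelihood), 1972 higher and 2103 lower, and the total was 2456 without combination 2 and 2464 without combination 3. Against gilteritinib 8439 changed, 4210 higher and 4229 lower. With total counts for scaling, the share of higher calls moved from 48.4% to 63.2% against MI-3454 and from 49.9% to 61.5% against gilteritinib, where the median log2 change shifted by 0.12. The largest rises over MI-3454 were in the cytokine receptor gene IL31RA (3.26 ± 0.19), OLR1 (2.81 ± 0.26), the cannabinoid receptor gene CNR2 (2.76 ± 0.13) and HLA-F (2.49 ± 0.21), and the largest falls in ADM2 (253-fold, exact 95% interval 69.6 to 2090), STC2 (80.3-fold, 21.9 to 669), DUSP8 (64.9-fold, 21.9 to 318) and CHAC1 (-5.36 ± 0.29). Over gilteritinib they were in CD14 (429-fold, 76.5 to 17000), ANKRD22 (161-fold, 28.5 to 6400), S100A8 (6.87 ± 0.29) and OLR1 (127-fold, 43.2 to 620). XIRP1, CD276, PKDCC and ADAMTS7 had no counts in the combination and were at least 133-fold, 61.8-fold, 58.3-fold and 54.5-fold lower than with gilteritinib. Cholesterol synthesis genes fell in 18 of 20 cases relative to MI-3454 (18 adjusted over the list alone; limma camera adjusted p = 1.18e-14, and adjusted p = 0.199 with an estimated correlation) and in 19 relative to gilteritinib (19 adjusted over the list alone; adjusted p = 1.34e-09, 0.137 with an estimated correlation). Fatty acid synthesis genes fell in 9 of 11 and in 10 of 11 cases (9 and 10 adjusted over the list alone; adjusted p = 2.18e-11 and 6.94e-07, or 0.199 and 0.169 with an estimated correlation).

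Relative to gilteritinib, ribosomal and mitochondrial genes were lower with the combination. Cytosolic ribosomal protein genes fell in 24 of 29 cases (24 adjusted over the list alone; limma camera adjusted p = 3.1e-05, and adjusted p = 0.433 with an estimated correlation), with a median log2 change of -0.41. Nuclear genes of oxidative phosphorylation fell in 14 and rose in 2 of 30 cases (13 and 2 adjusted over the list alone; adjusted p = 0.0208, 0.493 with an estimated correlation). With total counts 9 were lower and 4 higher, with a median of -0.11 in place of -0.23, and 21 were lower without the 4 libraries highest in RN7SL1. All 13 mitochondrially encoded genes fell (13 adjusted over the list alone; adjusted p = 0.00333, 0.48 with an estimated correlation). Their median was -2.73, or -1.30 without the 4 libraries highest in RN7SL1, of which gilteritinib 2 had the largest mitochondrial share. All 4 markers of mast cells, basophils and eosinophils fell (4 adjusted over the list alone; adjusted p = 0.000724, 0.137 with an estimated correlation).

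Genes changed in the same direction against DMSO and against both single agents numbered 3403, of which 1702 were higher and 1701 lower. The number was 2124 without combination 2 and 2103 without combination 3. Of them 1130 were already called in that direction with MI-3454 and 620 with gilteritinib. Of the 4904 genes called under the combination and under neither single agent, 2037 passed this stricter requirement. Among all 3403 genes, whether or not a single agent had changed them, IL31RA was 20.3 CPM with the combination. It was 2.21, 1.69 and 2.12 CPM with DMSO, gilteritinib and MI-3454. SEMA6B was 139 CPM with the combination against 14.1, 13.8 and 28.1 CPM in the same order. OLR1, HLA-F and SERPINB2 completed the 5 highest by the naming rule, and XIRP1, INHBE, PKDCC, ADM2 and CD276 were the 5 lowest. INHBE, a subunit of the activin family, had no counts with the combination and was at least 67.6-fold lower than with DMSO, 24.4-fold lower than with MI-3454 and 21.4-fold lower than with gilteritinib.

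The interaction term tested whether the combination departed from the sum of the log2 changes under the single agents, and 2136 genes did (edgeR quasi-likelihood), 915 above the sum and 1221 below it. The number was 1365 without combination 2, 1305 without combination 3 and 3478 without the 4 libraries highest in RN7SL1. Scaling by total counts moved the share above the sum from 42.8% to 58.1% and the median by 0.13. Below the sum lay MEIS1 (-1.54 ± 0.21, adjusted p = 0.000173), MEF2C (-1.52 ± 0.14, adjusted p = 4e-06), MYC (-0.79 ± 0.16, adjusted p = 0.00458) and SCD (-2.75 ± 0.17), and above it PIM1 (2.17 ± 0.16). HOXA9 (-0.24 ± 0.13, adjusted p = 0.223) and FLT3 (0.17 ± 0.15, adjusted p = 0.49) did not pass.

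S phase genes lay below the sum in 21 of 25 cases (24 adjusted over the list alone; limma camera adjusted p = 1.26e-14, and adjusted p = 0.0409 with an estimated correlation), with a median interaction of -0.74. The G2 and M phase genes did so in 19 of 23 cases (22 adjusted over the list alone; adjusted p = 1.88e-12, 0.0688 with an estimated correlation), and in 12 with total counts. Stem and progenitor genes lay below it in 5 of 8 cases (6 adjusted over the list alone; adjusted p = 5.39e-05, 0.0235 with an estimated correlation), GATA2 at -2.83 ± 0.22 after rising with gilteritinib alone and falling with MI-3454. Markers of mast cells, basophils and eosinophils lay below in 3 of 4 cases (3 adjusted over the list alone; adjusted p = 5.39e-05, 0.0235 with an estimated correlation), EPX at -3.52 ± 0.23. Fatty acid synthesis genes lay below in 8 of 11 cases (9 adjusted over the list alone; adjusted p = 1.83e-10, 0.0409 with an estimated correlation). MHC class II genes lay above it in 4 of 6 cases (4 adjusted over the list alone; adjusted p = 6.15e-06, 0.0235 with an estimated correlation), HLA-DRA at 5.48 ± 0.75, and interferon-stimulated genes in 7 of 22 (9 higher and 1 lower adjusted over the list alone; adjusted p = 6.61e-05, 0.0235 with an estimated correlation). Both groups had fallen with each single agent, and HLA-DRA had 0.239 CPM with gilteritinib, 1.19 with MI-3454 and 0.457 with the combination. HLA-DRB1 had 199 counts with DMSO, 1 with gilteritinib and 1 with the combination. Genes this low with a single agent could not fall by the sum of both changes, so their positive values rest on that limit.

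**Figure D5:**
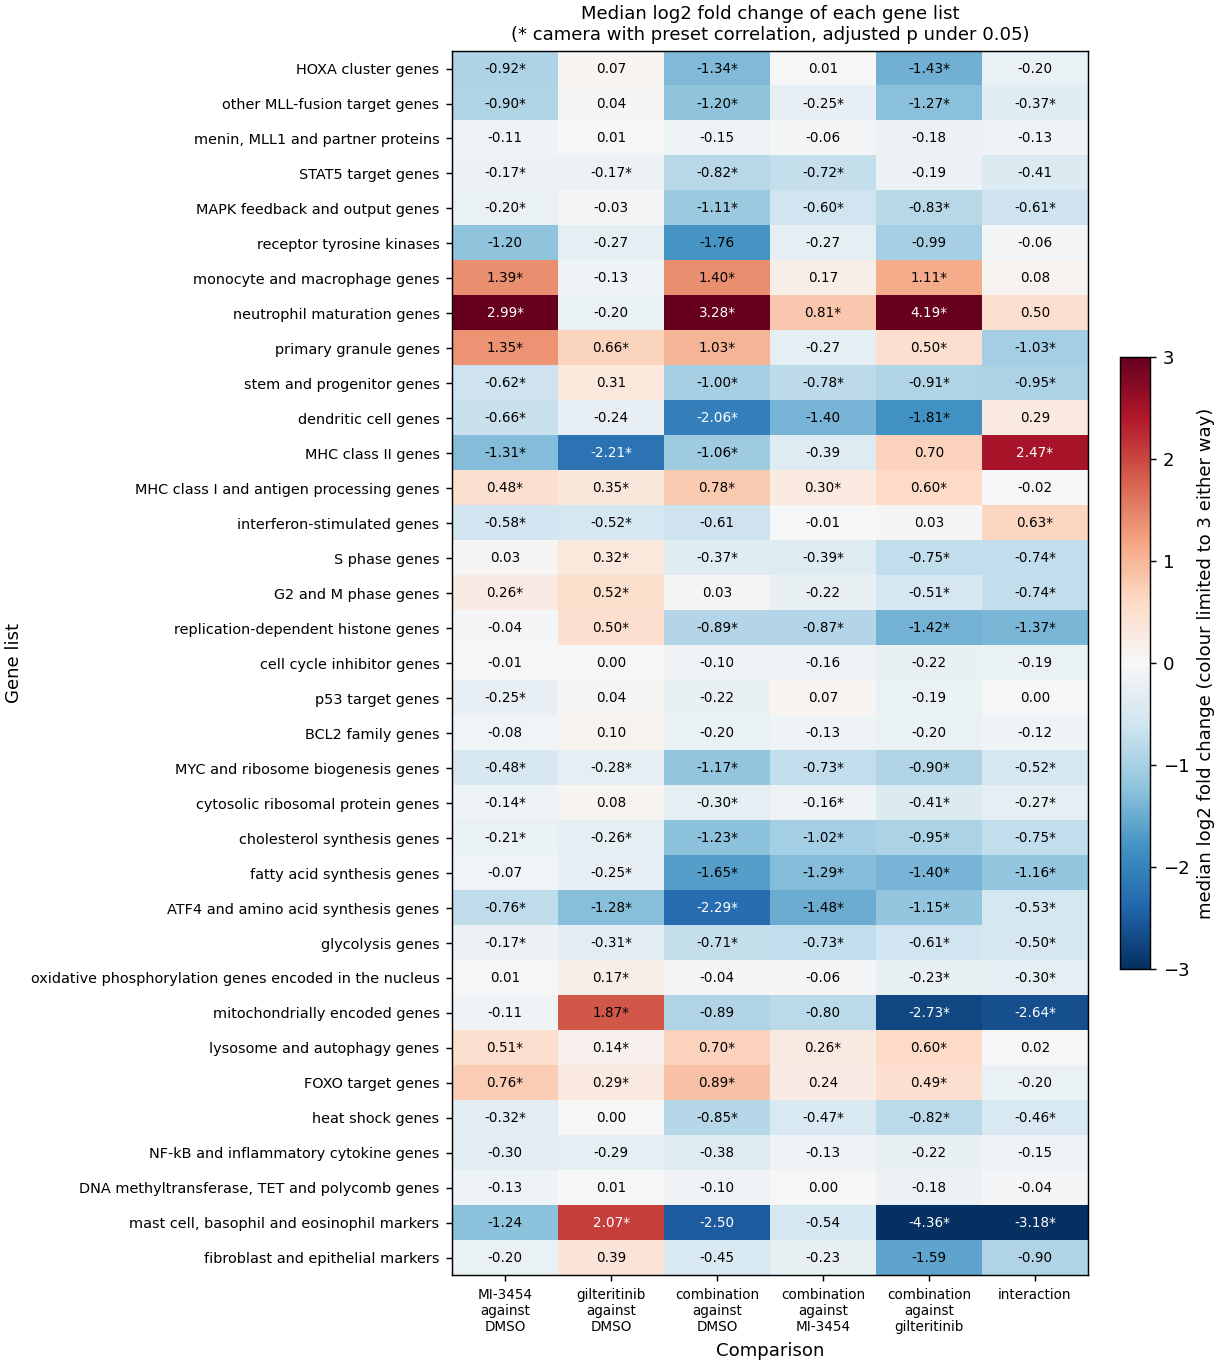
Median log2 fold change of the 35 gene lists with at least 3 tested members in each comparison, with colour from blue (lower) to red (higher) and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Neutrophil maturation genes have medians of 2.99 with MI-3454 and 3.28 with the combination against DMSO, and ATF4 and amino acid synthesis genes are lower in all 6 columns, from -0.53 to -2.29. For oxidative phosphorylation and cell cycle inhibitor genes the sign of the median against DMSO under the combination changes when total counts are used for scaling.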

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

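In this part, the alternative that subtracts a genomic background from the counts was chosen only after the first results were seen. A first group of results stands here because the effect of MI-3454 differed with and without gilteritinib by the interaction test. The log2 interaction was 8.89 for CD80, 7.09 for RHBDL3, 6.51 for IL2RA and 5.48 for HLA-DRA, and it was -7.30 for ADAMTS7, -7.30 for XIRP1, -6.04 for INHBE and -5.77 for DUSP8. CD80 had 181 counts with DMSO, 2 with gilteritinib, 0 with MI-3454 and 2 with the combination, so its positive value means that a gene close to 0 with each agent could not fall by the sum of both. RHBDL3 had 263, 3, 2 and 4 counts in the same order and IL2RA had 1706, 1, 30 and 2, so their values rest on the same limit and are not exact, and DUSP8 had 3 counts with the combination. HLA-DRA was likewise close to 0 with gilteritinib and with the combination. No counting interval was computed for an interaction. With the floor of 3 counts in place of 0, the interaction was 5.84 for CD80, -4.18 for ADAMTS7, -4.23 for XIRP1 and -2.95 for INHBE. The call ended for CD80 without combination 2 (6.20, edgeR adjusted p = 1), for RHBDL3 without combination 3 (3.48, adjusted p = 0.94), for IL2RA without combination 3 (3.79, adjusted p = 0.94) or with a genomic background subtracted (5.72, adjusted p = 0.098), and for ADAMTS7 without MI-3454 3 (-6.38, adjusted p = 0.078).

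The number of genes with an interaction was 2136. Of 100 splits of the libraries, 2 gave as many, the real one included. The highest of the others was 3511, in a split that keeps the 3 combination libraries together. Another split that keeps them together gave 135, and the source of the difference was not tested. Most splits mix the treatments and so raise the spread within groups, which lowers their counts whether or not there is an interaction, so the share does not exclude chance for the interaction itself. For MI-3454, gilteritinib and the combination against DMSO, and for the combination against MI-3454 and against gilteritinib, only the real split of 10 gave as many genes (1 of 10 in each of the 5 comparisons). The real values were 2658, 2110, 8037, 4075 and 8439, and the highest other was 0 in each, but 10 splits are too few for a share under 0.05.

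Reads outside annotated exons are a signal in counts that the comparisons do not use, and they took 32.6% of uniquely placed reads with the combination, above the DMSO libraries. Genomic DNA in these libraries would lift genes of silent families as much as reads spread evenly over the genome. The rise over those families was 0.145 of the even rise (0.0847 to 0.218 over the libraries), although the families rose 2.55-fold. The low ratio argues against genomic DNA as the whole cause if such reads are counted in full over these families. Strand-specific counting, whose setting is not given, or loss of reads at near-identical copies would lower the rise that genomic DNA gives there. By how much was not tested. More unspliced RNA would lift sense-intronic transcripts by more than an even spread, and their rise was 5.95 times the even one (2.66 to 8.67), 1.76-fold over DMSO. That is what more unspliced RNA needs but does not establish it, since the share of all reads outside exons rose from 18.1% to 32.6%, about as much, and whether treatment or handling caused the rise was not tested.

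More genes were at least 2-fold higher than at least 2-fold lower under the combination, 1929 against 1432, a ratio of 1.35. An even background along the genome, at the density of the silent families, would bring the ratio down to 1 on subtraction if it were the cause, and the ratio was 1.31 (1917 against 1459). Library scaling would do so under another scaling, and the lower of the ratios under 2 other scalings was also 1.31, the other being 1.74 with total counts. The values argue against an even background of that density as the whole cause. They do not decide on scaling, because no scaling used had a reference outside the counts and 8037 of 13972 genes changed. The density subtracted was small, so a background within transcribed regions stays open, as does a wider activation of genes in the treated cells, and neither was tested.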

How the results depend on the processing

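Leaving out 4 libraries together, subtracting a genomic background and leaving out each library from the overlaps were chosen after seeing the data. Of 416 pairs of a named gene and a comparison, 342 had the same call under each setting run for them. A replicate block gave 1678 genes with MI-3454 and 4928 with gilteritinib against DMSO. Over the 4 groups 6 of 18 same-number pairs correlated above 0.1 (3 of 3 for DMSO and gilteritinib) and 3 libraries correlated best with their own number. Without the 4 libraries each highest in RN7SL1 within their group, 4250 genes changed with gilteritinib, 3478 in the interaction and 1694 in all 3 lists. A 2-fold minimum left 277 genes in all 3 lists and 894 beyond both single agents. With an estimated correlation 1 list was called with MI-3454, 1 with gilteritinib, 0 with the combination, 0 against MI-3454, 0 against gilteritinib and 6 in the interaction. Leaving out 1 library gave 1243 (without gilteritinib 3) to 3985 (without DMSO 2) genes with gilteritinib, 2456 (without combination 2) to 5074 (without MI-3454 3) for the combination against MI-3454, and 1305 (without combination 3) to 2698 (without DMSO 2) in the interaction. It gave 585 (without DMSO 1) to 1349 (without DMSO 2) genes in all 3 lists and 2103 (without combination 3) to 3652 (without MI-3454 3) beyond both agents. MT-ATP6 in the combination against DMSO reversed to 0.17 without DMSO 2, not called (edgeR adjusted p = 0.42), and was -1.70 without DMSO 3. MT-ND2, MT-ND3 and MT-ATP8 also lost their calls without DMSO 2, at -0.17, -0.14 and -0.22. The size of these falls thus depended on DMSO 2, and the combination and DMSO libraries overlapped for all 4 genes. All 4 calls also ended with all 12 libraries in a single fit. Those of MT-ATP6, MT-ATP8 and MT-ND3 ended without combination 3 as well. The call of MT-ND2 was not among those that ended without the 4 libraries, which include DMSO 2. Why DMSO 2 differed was not tested.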

Other observations

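The library with the highest RN7SL1 share in each group was singled out only after the data were seen. MOLM-13 cells with DMSO carried the myeloid regulators CEBPA at 672 ± 80.7 CPM (mean ± SD, n = 3) and SPI1 at 265 ± 56.7 CPM. MYB, which MLL-rearranged leukaemias depend on, stood at 504 ± 23.6 CPM, and the HOXA9 cofactor gene PBX3 at 139 ± 7.72 CPM. Among surface markers found on myeloid cells, CD4 was at 388 ± 24.8 CPM, CD33 at 92.5 ± 8.97 CPM and the M-CSF receptor gene CSF1R at 86.5 ± 7.83 CPM. Other myeloid genes were nearly absent with DMSO: FCN1 had no counts, and S100A9 stood at 0.546, 0.57 and 0.432 CPM. Lysozyme (LYZ) stood at 415 ± 37.5 CPM while MCL1 was at 276 ± 16 CPM and BCL2L1 at 22.4 ± 2.64 CPM.

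Pearson correlations of log2 CPM were 0.987 and 0.984 for pairs with DMSO 2 against 0.990 for the remaining pair, 0.988 and 0.988 with gilteritinib 2 against 0.993, and 0.985 and 0.982 with MI-3454 3 against 0.990. They were 0.992 and 0.988 for pairs with combination 1 against 0.990, so combination 1 did not stand apart by this measure. Chi-square per degree of freedom between libraries of a group was 17.4 and 23.2 for pairs with DMSO 2, 16.5 and 21.0 for pairs with gilteritinib 2, and 20.4 and 25.9 for pairs with MI-3454 3. It was 5.38, 2.03 and 3.64 for the remaining pair of each of these groups. For the combination it was 4.17 and 6.74 for pairs with combination 1 and 2.57 for the remaining pair, a measure that grows with depth, and combination 1 was the deepest of its group. The labels name no batch, and no explanation was tested.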
